A study of Homo sapiens with 4 samples.

How the data were processed

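Ribosome footprint and input RNA libraries of HepG2 cells were used, 1 of each from METTL5 knockout cells and 1 of each from vector control cells, 4 libraries in 4 groups. Per the labels' protocols, METTL5 was knocked out with a guide RNA, RNA was taken up in TRIzol, and libraries came from a stranded mRNA kit, a mammalian ribosome profiling kit and a small RNA kit. Per the submitters' processing notes, Trim Galore, Bowtie and the genome build hg38 were used, with no versions or roles. The read counter, the annotation, the strand setting and the scaling of the libraries are not given in the sources used here.

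The authors deposited 1 table of 58302 genes with a ratio per gene under each of the 4 library names and a fold. For 57694 genes the value under the input name was identical to the value under the footprint name of the same genotype, so the table holds 1 ratio per genotype and no separate input and footprint values. Under the input names, 363 genes in the knockout and 343 in the vector had an infinite value, which only a division by 0 gives, and 608 genes with an infinite value in either genotype had no value under the footprint names. The deposited fold matched the quotient of the knockout and vector ratio for all 10736 genes with both ratios above 0, within the rounding of the ratios to 2 decimals. The ratio was taken as footprint over input. The table does not state this, and if it were input over footprint every direction would turn around.

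The design fixed before the data were examined assumed read counts. The planned comparisons of mRNA level and of footprint level, the scaling with size factors, the count minimum of 30 and the counting intervals need counts and were not run. In their place, the log2 fold was the log2 quotient of the knockout and vector ratio, with no pseudocount, over genes with both ratios above 0. A gene was called higher or lower when the fold was at least 2 and the interval allowed by rounding (0.005 either way on each ratio) excluded no difference. This interval covers rounding only. The depth behind a ratio is unknown, so no counting interval is given, and with 1 library per group there is no test and no p-value.

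The 30 gene lists (837 entries, 42 of them found under an older symbol) were written before the data were examined. For each list with at least 5 measured genes, the median log2 fold was placed among the medians of 10000 random lists of protein-coding genes of the same size, matched on the mean log2 ratio in 20 bins. The named genes follow a rule fixed at the same time: METTL5, TRMT112 and ACSL4 always, the 10 highest and 10 lowest genes by the interval bound nearest 0, and per list up to 2 members in each direction that met the 2-fold rule, or the 2 with the largest absolute log2 fold where none did. Because 8 of the 10 highest genes were not protein-coding, the 10 highest and 10 lowest protein-coding genes were added after the data were seen. Other members named as examples (ALB, AFP, SERPINA1, HSP90B1, HSPA5, FASN, ACSL1, ACSL3, ACSL5, ATF4, DDIT3, MT-ATP8, EEF1G, SFN) were chosen after their values were seen. Coordinates come from the RefSeq genes of GRCh38, the assembly that hg38 names. Gene symbols and types are those of the deposited table.

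The calculation was tested on simulated data made from the vector ratios of 10736 genes, with 200 genes changed and a log2 noise SD of 0.3. It recovered 6% of genes changed 1.5-fold, 89.5% of those changed 2.5-fold and 100% of those changed 4-fold, called 0 in the wrong direction and 9 to 14 unchanged genes. The noise was the same at every ratio, and genes of the lowest vector ratios were not among those changed. Across the real genes the log2 fold had an SD of 0.87, real differences included, so these rates do not carry over to the data. A simulated list of 40 genes raised 1.4-fold lay at percentile 100, and 3 of 40 unshifted lists fell outside the central 95%. Alternatives were a fold of 1.5, the whole rounding interval beyond 1.5-fold, pseudocounts of 0.1, 1 and 10, leaving out abundant gene families, protein-coding genes alone, centring on the median of all measured genes, windows of mean ratio, no rounding interval, and random lists without matching. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used.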

Results

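HepG2, an established human cell line from a hepatocellular carcinoma, was profiled with and without METTL5, the methyltransferase that places an N6-methyladenosine on 18S ribosomal RNA. Cells in which METTL5 had been knocked out with a guide RNA were compared with cells that carried the vector alone, to find genes translated differently between them. Each genotype had 1 ribosome footprint library (Ribo-seq, which sequences the mRNA fragments that ribosomes protect) and 1 matching input RNA library. The 4 libraries form 4 groups of 1, so no difference reported here has a replicate check and no p-value is given. The deposited table lists 58302 genes with 1 ratio per genotype, taken here as footprint over input and called the footprint/input ratio, a measure of translation efficiency. The table does not state what was divided by what, its values are not read counts, and the depth of the 4 libraries is unknown. The mRNA level and the footprint level on their own were not analysed here.

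The gene targeted by the guide RNA, METTL5 (ENSG00000138382, GRCh38 chromosome 2, 169811757 to 169824905), had a footprint/input ratio of 2.98 in the vector control and 0.76 in the knockout. The ratio was 3.92-fold lower in the knockout, a log2 fold of -1.97, and rounding of the deposited values allows -1.98 to -1.96. Among 10291 protein-coding genes with a ratio in both genotypes, 178 had a log2 fold at or below that of METTL5, or 1.73%. The ratio holds no information on how much METTL5 RNA each library contained, so it checks the genotype labels only in part. TRMT112 (ENSG00000173113, chromosome 11, 64316460 to 64318596), the protein partner that stabilises METTL5, had ratios of 1.35 and 1.20, a log2 fold of -0.17. ACSL4 (ENSG00000068366, chromosome X, 109641335 to 109733257), which activates long polyunsaturated fatty acids as acyl-CoA, had ratios of 1.30 and 0.98, a log2 fold of -0.41 at percentile 29.8 of the protein-coding genes. The fold in the authors' deposited table was 0.26 for METTL5, 0.89 for TRMT112 and 0.75 for ACSL4.

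Footprint/input ratios differed in both directions in about equal numbers. Of 10736 genes with both ratios above 0, 1086 were at least 2-fold higher in the knockout and 1038 at least 2-fold lower, together 19.8%. Among the 10291 protein-coding genes, 934 were higher and 979 lower, and among the 445 genes of other types 152 and 59. The balance depends on the scaling of the libraries, which is not given. Centring on the median of all measured genes gave 1212 higher and 883 lower. The highest protein-coding genes included UBXN11, a UBX domain protein, with 0.22 in the vector and 3.6 in the knockout. They also included RAPGEF6, an exchange factor for Rap GTPases (0.10 and 1.42), TRAIP, a ubiquitin ligase of the replication machinery (0.21 and 2.53), and BPGM, which makes bisphosphoglycerate (0.36 and 3.63). CHMP3, a subunit of the ESCRT-III membrane remodelling complex, had ratios of 0.03 and 0.42, and the RNA-binding repressor SAMD4A had 0.04 and 0.48. The transcription factor ZNF143 had 0.20 and 2, the microtubule-associated protein EML3 0.08 and 0.82, KIAA2026 0.04 and 0.59, and POGK 0.02 and 0.28.

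The lowest protein-coding genes in the knockout included KIF18A, a kinesin that limits chromosome movement in mitosis, with 3.30 in the vector and 0.16 in the knockout. ERI1, an exoribonuclease that trims histone mRNA, had ratios of 1.61 and 0.09, and PUS3, a pseudouridine synthase for transfer RNA, had 2.28 and 0.17. The sulfotransferase CHST7 had 2.06 and 0.11, the cyclic AMP phosphodiesterase PDE8A 0.45 and 0.03, and the death effector domain protein DEDD2 0.96 and 0.08. PQLC3 had 3.76 and 0.20, the RNA-binding protein RBM48 1.28 and 0.12, and KCTD6 1.66 and 0.16. MTRNR2L12 had 43.71 and 1.09, the lowest log2 fold at -5.33, and is uncertain because it is a nuclear copy of the mitochondrial large ribosomal RNA and shares reads with it. Its vector ratio also lies within 0.0075 of 2 times 21.8515, a step on whose simple fractions 76.7% of the vector ratios from 5 to 100 lay.

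Across the protein-coding genes the median ratio was 0.72 in the vector (interquartile range 0.39 to 1.28) and 0.68 in the knockout (0.39 to 1.15). The median log2 fold was -0.10 with an SD across genes of 0.83, and the ratios of the genotypes had a Pearson r of 0.77 and a Spearman rho of 0.78 on the log scale across genes, which are not independent replicates. The counts depend on any constant added to the ratios. With 1 added to every ratio, which is more than the median ratio, 135 genes were at least 2-fold higher and 120 lower. Leaving out genes of a mean ratio below 0.1 changed little, with 1041 higher and 1016 lower. A further 1116 genes were listed at 0 in the knockout alone and 965 in the vector alone, and 44877 were listed at 0 in both. No fold is given for any of these, because genes that every cell uses, such as the elongation factor EEF1G, are also listed at 0.

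**Figure D1:**
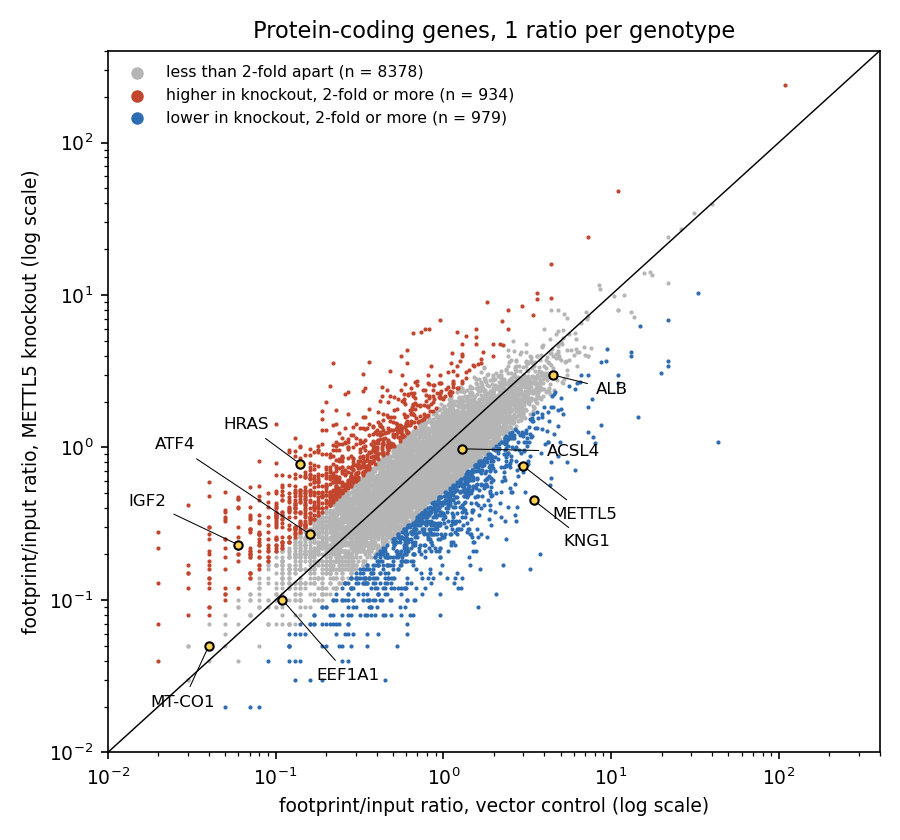
Footprint/input ratio of each protein-coding gene in the vector control (x axis, log scale) against the METTL5 knockout (y axis, log scale), 1 ratio per genotype and gene, with the line of equal ratios. The 934 red genes were at least 2-fold higher and the 979 blue genes at least 2-fold lower in the knockout, and METTL5 lies among the blue genes at 2.98 and 0.76.

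Of the secreted proteins of hepatocytes and the endoplasmic reticulum chaperones, most had lower ratios in the knockout by less than 2-fold. The secreted proteins had a median log2 fold of -0.39 over 36 measured genes, with 31 below 0 and 3 above. Serum albumin ALB had ratios of 4.50 in the vector and 2.99 in the knockout, alpha-fetoprotein AFP 3.02 and 2.06, and the protease inhibitor SERPINA1 2.29 and 1.54. The 2 members at least 2-fold lower were kininogen KNG1 (3.47 and 0.45) and the fibrinogen chain FGB (2.49 and 1.24, where rounding allows a log2 fold as small as -0.997), and none was at least 2-fold higher. This median lay at percentile 2.12 of 10000 random gene lists of the same size and mean ratio. Those lists had a median of -0.20, so part of the -0.39 is shared by genes of this ratio level. Against the median of all protein-coding genes, 30 members lay below and 6 above. Endoplasmic reticulum stress genes and chaperones had a median of -0.40 over 24 genes, with 21 below 0, at percentile 2.61, inside the central 95% of random lists. The random lists matched to them had a median of -0.16. The chaperone HSP90B1 had ratios of 2.76 and 1.6 and HSPA5 1.95 and 1.35, both under 2-fold apart, and the oxidase ERO1B (1.54 and 0.47) was the 1 member at least 2-fold lower.

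Most ribosome biogenesis factors had lower ratios in the knockout, with a median log2 fold of -0.33 over 44 genes, 33 below 0 and 10 above. TBL3, a component of the small subunit processome, had ratios of 1.45 and 0.53, and BRIX1, a large subunit assembly factor, had 3.51 and 1.34. These were the 2 members past 2-fold, and the median lay at percentile 2.03 of the random lists, whose own median was -0.15. The enzymes that modify ribosomal RNA, a list that holds METTL5 itself, had a median of -0.18 over 18 genes at percentile 39.9. EMG1, a methyltransferase of the small ribosomal subunit, was lower at 0.51 and 0.12. It is uncertain, because a second entry of the same symbol is listed at 0 in both genotypes. ZCCHC4, the methyltransferase for N6-methyladenosine of the large subunit RNA, was higher at 0.77 and 1.56.

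The cytosolic ribosomal proteins themselves differed little. Of 78 measured genes 74 were within 2-fold, and their median log2 fold was -0.11 at percentile 20.04. RPL36AL (0.32 and 0.15) and RPL17 (0.81 and 0.38) were lower, and RPS2 (0.04 and 0.08) and RPL13A (0.06 and 0.12) were higher. These are uncertain, since ribosomal protein genes have many pseudogene copies, and rounding alone allows a log2 fold of 0.74 to 1.28 for RPS2 and 0.82 to 1.18 for RPL13A. Elongation factors and other mRNAs with a terminal oligopyrimidine start had a median of -0.11 over 15 genes at percentile 28.0, with EIF4B as the 1 member past 2-fold, at 0.05 and 0.11, where rounding allows a log2 fold of 0.93 to 1.35. Initiation factors had a median of -0.24 over 36 genes at percentile 12.7. EIF4EBP2, which binds and blocks the cap-binding protein, was higher (0.07 and 0.22). EIF2B1, a subunit of the exchange factor for eIF2, was lower (1.34 and 0.60), as was EIF3C (0.72 and 0.33), which shares reads with a near-identical copy and is uncertain. The mRNA m6A machinery had a median of 0 over 19 genes and of 0.08 after centring on the median of all measured genes, at percentile 63.2. Its members CBLL1 (0.29 and 0.85) and RBM15B (0.04 and 0.09) were higher and ZC3H13 (1.92 and 0.82) was lower, all parts of the methyltransferase complex, and rounding allows 0.92 to 1.44 for RBM15B.

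Lipid metabolism showed few differences past 2-fold. None of the 18 fatty acid synthesis genes met the 2-fold rule, and their median log2 fold was -0.10 at percentile 58.9. ACACA, the carboxylase that commits acetyl-CoA to fatty acids, had ratios of 0.93 and 0.55, the reductase TECR had 3.30 and 2.01, and FASN had 0.88 and 0.89. Genes of fatty acid activation and uptake had a median of -0.06 over 22 genes, which became 0.02 after centring on all measured genes, at percentile 66.7. The fatty acid transporter CD36 (1.99 and 3.98) was its 1 member at 2-fold, with 0.99 to 1.01 allowed by rounding. That range covers rounding alone, and both CD36 ratios may rest on very few reads, which was not checked. ACSL3 (1.64 and 1.09), ACSL5 (1.55 and 1.13) and ACSL1 (0.91 and 0.65) had lower ratios by less than 2-fold. Beta-oxidation genes had a median of -0.03 over 25 genes, 0.06 after the same centring, at percentile 82.9, with the dienoyl-CoA reductase DECR2 higher at 0.14 and 0.53. Of 23 cholesterol synthesis genes none met the rule, with a median of -0.09 at percentile 72.6. SQLE had ratios of 2.15 and 1.29 and IDI1 had 2.37 and 1.46. Ferroptosis and glutathione genes had a median of -0.13 over 19 genes at percentile 47.9 and none past 2-fold, with KEAP1 at 0.59 and 1.03 and GSR at 0.73 and 0.54. Selenoproteins had a median of -0.18 over 19 genes at percentile 32.8, and SELENOM was lower at 1.12 and 0.33.

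Mitochondrially encoded proteins had slightly higher ratios in the knockout in 12 of 13 genes, and the remaining MT-ATP8 was equal at 0.31. Their median log2 fold was 0.29 at percentile 87.4, none reached 2-fold, and the largest differences were in the complex I subunits MT-ND4L (0.28 and 0.46) and MT-ND1 (0.25 and 0.36). The nuclear-encoded oxidative phosphorylation genes had a median of -0.22 over 47 genes at percentile 44.5. The complex I subunit NDUFB8 was higher (1.52 and 3.41), and NDUFA9 (3.34 and 1.18) and the cytochrome oxidase subunit COX6A1 (0.42 and 0.15) were among 3 that were lower. Mitochondrial ribosomal proteins had a median of -0.23 over 45 genes at percentile 21.4, with 3 higher and 3 lower. MRPL38 (0.56 and 3.98) and MRPS6 (0.59 and 2.62) were higher, and MRPL1 (4.32 and 0.57) and MRPL24 (3.12 and 1.25) were lower. Glycolysis genes had a median of 0.03 over 22 genes at percentile 91.7, and their 3 members past 2-fold all concern the phosphofructokinase step. PFKP (0.42 and 2.02) and PFKFB3 (0.42 and 1.38), which makes its activator, were higher, and PFKM (3.90 and 1.33) was lower.

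Targets of ATF4 and the integrated stress response had a median log2 fold of -0.07 over 28 genes, 0.01 after centring on all measured genes, at percentile 67.0, with 18 below 0 and 10 above. The transcription factor ATF3 was the 1 member past 2-fold (0.27 and 0.69), and ATF4 itself (0.16 and 0.27) and DDIT3 (0.36 and 0.62) were among the 10 above 0. Cytosolic heat shock proteins had a median of -0.28 over 20 genes at percentile 17.7, with none past 2-fold, DNAJB4 at 1.28 and 0.65 and HSPA4 at 2.58 and 1.53. Targets of p53 had a median of -0.31 over 20 genes at percentile 9.4, with the kinase PLK3 higher (0.29 and 0.60) and the repair protein XPC lower (1.59 and 0.48). Proteasome genes had a median of -0.09 over 30 genes at percentile 84.2 and none past 2-fold, with PSMA5 at 3.68 and 2.12 and PSMD6 at 2.42 and 1.66. Interferon response genes had a median of -0.06 over 22 genes, 0.03 after centring, at percentile 79.0, with the RNA sensor IFIH1 lower at 1.81 and 0.62.

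Cell cycle genes had a median log2 fold of 0.05 over 36 genes at percentile 96.4, with 3 members higher and 3 lower. The mitotic kinase AURKB (0.87 and 2.40) and cyclin CCNE1 (0.78 and 1.61) were higher, and the spindle kinesin KIF11 (1.94 and 0.49) and the ribonucleotide reductase subunit RRM2 (0.77 and 0.28) were lower. Replication-dependent histones had a median of 0.09 over 20 genes at percentile 97.3, with HIST2H4A (2.43 and 7.96) and HIST1H2BK (0.28 and 0.65) higher and HIST1H1B (3.18 and 0.82) and HIST1H4A (14.90 and 6.23) lower. Histone genes have near-identical copies and are uncertain. Growth signalling genes and oncogenes had a median of -0.20 over 30 genes at percentile 14.6, with the GTPase HRAS (0.14 and 0.78) and the growth factor IGF2 (0.06 and 0.23) higher and none lower past 2-fold. IGF2 overlaps a read-through gene with insulin and is uncertain. Genes of the epithelial to mesenchymal transition had a median of -0.42 over 17 genes at percentile 3.55, and their 1 member past 2-fold, the integrin ITGA5, was higher (0.50 and 1.04).

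Of the 27 lists with at least 5 measured genes, 22 had a median below 0, 4 above and 1 at 0. The median of all measured genes was itself -0.08, and after centring on it 18 lists lay below 0 and 9 above. The secreted proteins and the ribosome biogenesis factors were the 2 lists outside the central 95% of random lists, where 1.35 would fall outside by chance. With mean ratios from 0.3 to 3 the secreted proteins lay inside, at percentile 2.85, and without matching on the mean ratio the endoplasmic reticulum list also lay outside, at 2.13. Markers of cell types other than hepatocytes were mostly not measured. Of 18 blood cell genes LYZ (2.81 and 1.85) and CD14 (2.73 and 3.18) had both ratios, and of 14 fibroblast and endothelial genes PDGFRB did (0.46 and 0.59). Of 13 squamous, neural and germ line genes TUBB3 (3.64 and 9.38) and SFN (1.47 and 1.05) did. The percentiles describe these libraries and are no test of the genotype.

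**Figure D2:**
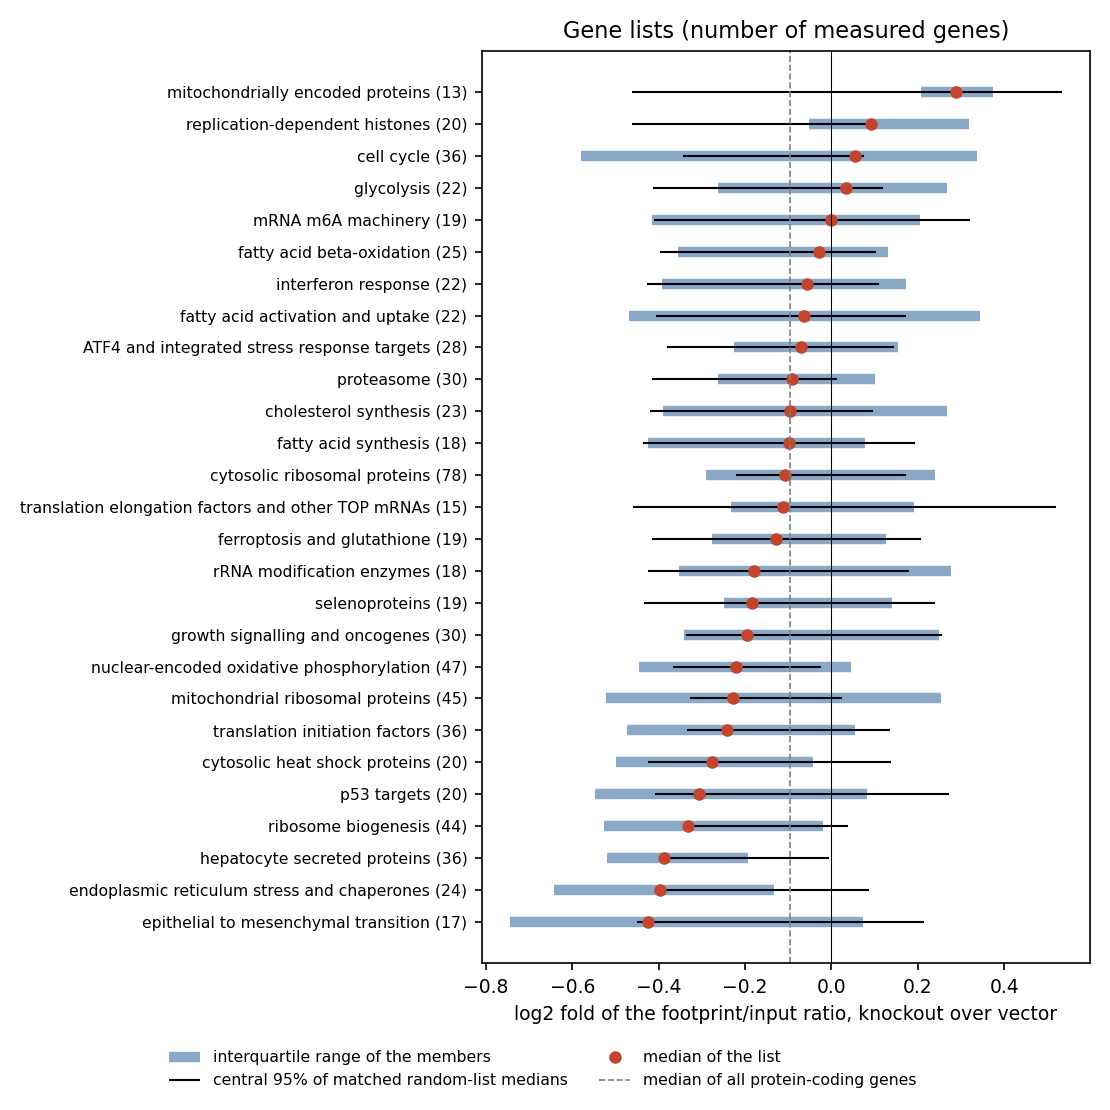
Median log2 fold of the footprint/input ratio, knockout over vector, for 27 gene lists (red points, number of measured genes in brackets), with the interquartile range of the members (blue bars), the central 95% of medians of matched random lists (black lines) and the median of all protein-coding genes (dashed line). The lowest medians are those of the epithelial to mesenchymal transition (-0.42), the endoplasmic reticulum list (-0.40) and the secreted proteins (-0.39), and the highest is that of the mitochondrially encoded proteins (0.29).

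Short nuclear RNAs, which are not translated, had higher ratios in the knockout. The 21 genes annotated as small nuclear RNA, pseudogene copies included, had a median log2 fold of 1.54, with 14 at least 2-fold higher and 1 lower. The 78 small nucleolar RNAs, most of which guide ribosomal RNA modification, had a median of 0.98, with 37 higher and 6 lower, and the 10 small Cajal body RNAs had 1.20, with 5 higher and 0 lower. Among the 10 genes of any type highest in the knockout, SCARNA1 had ratios of 2.30 and 250.81, SNORD46 0.73 and 19.11, SNORA80C 16.39 and 238.87, and SNORA74B 0.43 and 5.72. RNU5F-1 (9624.9 and 154763), RNU5A-8P (101.98 and 1337.66), RNVU1-7 (0.01 and 0.26) and the pseudogene AC020904.2 (0.73 and 9.84) were also among them and are uncertain, because they belong to families of near-identical copies. SNORA26 (16.39 and 0.80) and the pseudogene AC105250.1 (58.28 and 3.98) were among the 10 lowest. Of the 7 ratios from 5 to 100 among the highest and lowest genes, 4 lay on simple fractions of the step of their genotype. These were MTRNR2L12, SNORA80C and SNORA26 in the vector and SNORD46 in the knockout. The vector ratio of AC105250.1, at 2.667 steps, missed such a fraction narrowly. Of all ratios in this range, 76.7% in the vector and 73.55% in the knockout lay on such fractions, against at most 42.1% and 46.8% for decoy steps. The 7 values therefore do not set these genes apart. The 12 mitochondrial transfer RNAs had a median of -0.89, with 3 higher and 5 lower. Long intergenic non-coding RNAs had a median of 0.55 over 82 genes and antisense RNAs of 0.31 over 89. The counting strand is not given in the sources used here, so antisense genes cannot be told from their partners. The ratio of such RNAs is no translation efficiency, and no replicate shows how far it varies between libraries.

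**Figure D3:**
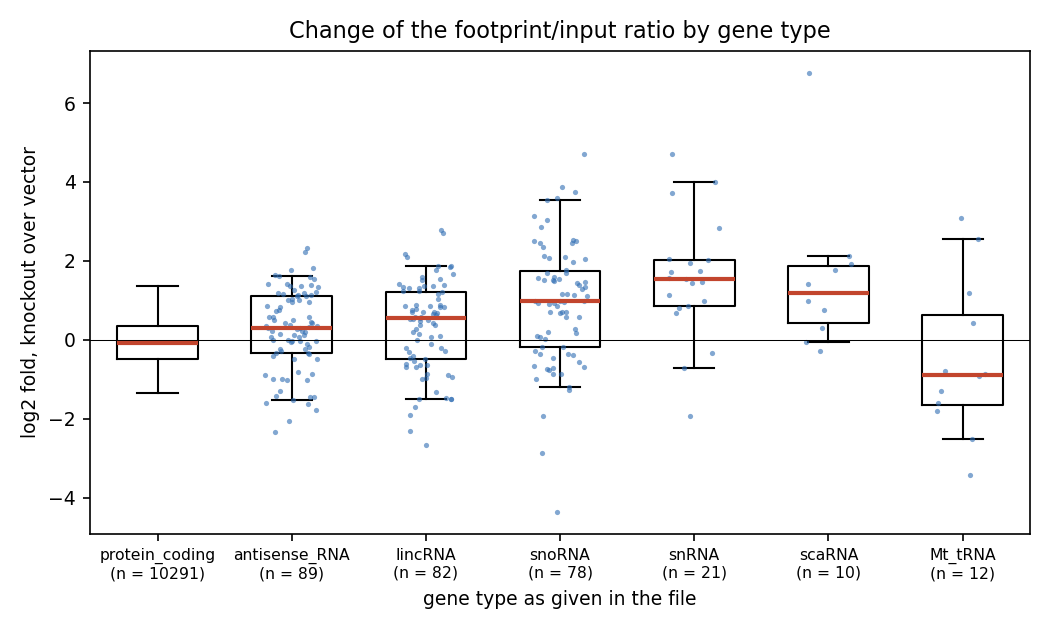
Log2 fold of the footprint/input ratio, knockout over vector, by gene type as the deposited table gives it. Red lines are medians, boxes interquartile ranges, whiskers the central 90% of genes and points single genes for types with fewer than 100, and the medians of small nuclear (1.54), Cajal body (1.20) and nucleolar RNAs (0.98) lie above that of protein-coding genes (-0.10).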

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

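A signal outside the ratios compared above was found under the input names of the table, where 363 genes in the knockout and 343 in the vector control had an infinite ratio, and 98 of them had it in both. These genes have no place in the report's comparisons, since an infinite ratio has no fold. By type, 271 of the 608 genes with an infinite ratio in at least 1 genotype were processed pseudogenes, 80 were protein-coding and 63 were small nuclear RNAs. No explanation was tested for them.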

How the results depend on the processing

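Pseudocount 1, protein-coding genes alone, centring, the windows of mean ratio, leaving out the rounding interval and random lists without matching were chosen after seeing the data. The main counts were 1086 genes higher and 1038 lower. A fold of 1.5 gave 2037 and 2288, since the threshold is lower. Pseudocounts shrink every fold by construction, those of low ratios most. They gave 722 higher and 719 lower at 0.1, 135 and 120 at 1, and 45 and 18 at 10. At 10 the share of higher genes was 71.4% against 51.1%. Keeping mean ratios from 0.3 to 3 gave 653 higher and 747 lower, over fewer genes. Centring on the median of all measured genes gave 1212 and 883, a share of 57.9%. The other settings left both counts within 1.5 times the main ones. The log2 fold of METTL5 was -1.84, -1.18 and -0.27 with pseudocounts 0.1, 1 and 10, and -1.89 after centring, against -1.97. The 95 named genes kept their sign under the pseudocounts and centring, but this was fixed in advance. A pseudocount added to both ratios cannot turn a sign. Centring only takes away the median of -0.08, and the named log2 fold nearest 0 was that of TRMT112 at -0.17. Of the list medians, that of the mRNA m6A machinery was 0 and became 0.08 after centring (and 0.0084 with mean ratios from 0.3 to 3). Centring also turned 4 others to above 0, at 0.02 for fatty acid activation, 0.06 for beta-oxidation, 0.01 for ATF4 targets and 0.03 for the interferon response. The secreted proteins moved from percentile 2.12 of random lists to 2.85, inside the central 95%, with mean ratios from 0.3 to 3. Without matching, 3 lists lay outside, with the endoplasmic reticulum list moving from 2.61 to 2.13, and the ribosome biogenesis factors lay outside in both cases, at 2.24 and 1.57. Other size factors, total-count scaling, count minimums, thinning and a prior count need read counts and were not run. No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. Depth is unknown, so the error of a single ratio cannot be given.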

Other observations

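The tests below on the size of the ratio step, on abundant families, on mitochondrial transfer RNAs and on small RNAs of low ratio were chosen only after the result was seen. The level of the ratio differed widely between gene groups in both genotypes. In the vector control the highest list medians were those of nuclear-encoded oxidative phosphorylation (2.30, and 1.94 in the knockout), secreted proteins (2.28 and 1.75) and the proteasome (2.09 and 2.02). Among the 4 lowest were those of mitochondrially encoded proteins (0.31 and 0.42), elongation factors and other terminal oligopyrimidine mRNAs (0.44 and 0.41) and cytosolic ribosomal proteins (0.49 and 0.41). This order rests on reading the ratio as footprint over input, and would turn around if it were input over footprint. EEF1A1, the main elongation factor, had ratios of 0.11 and 0.10, and the ferritin chains had 0.15 and 0.16 for FTH1 and 0.16 and 0.19 for FTL. The ribosomal protein genes are uncertain because of their pseudogene copies. Whether reads of EEF1A1 and the ferritin chains are lost to copies was not tested, so these low ratios need not mean low translation. The nuclear long RNAs had low ratios too, at 0.23 and 0.07 for MALAT1 and 0.04 and 0.09 for NEAT1.

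Gene families named mostly for secreted or endoplasmic reticulum proteins, outside the fixed lists, had a low median too. The 112 genes were picked by the start of their symbol, so some are neither, such as the nuclear C1D, the mitochondrial APOO and the intracellular SERPINB1. Their median log2 fold was -0.30, with 6 at least 2-fold lower and 1 higher. The lower ones were the laminin chains LAMA3 (1.11 and 0.24) and LAMC3 (0.85 and 0.33), the coagulation factor F12 (3.18 and 0.78), the lysosomal protease CTSV (4.05 and 1.05), complement factor CFD (1.5 and 0.39) and C4B (0.34 and 0.14), which has a near-identical copy and is uncertain. IGFBP3, which binds insulin-like growth factors, was higher (0.27 and 0.85).

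The lower ratios of secreted protein and endoplasmic reticulum mRNAs had a median of -0.39 over the 60 genes of both lists, which were joined because both were seen to be low. Random lists matched to the 2 lists had medians of -0.20 and -0.16, so part of the shift is shared by genes of that ratio level. Loss of membrane-bound ribosomes from the knockout lysate would lower transporters and transmembrane proteins too. The 326 SLC and TMEM genes had a median of -0.11 at percentile 65.39, which argues against a loss common to them. They were picked by symbol and need not all be translated at the endoplasmic reticulum, so a loss limited to some membrane-bound ribosomes is not excluded. The choice of list members alone is argued against by the 112 genes picked by symbol, at percentile 0.79 of matched random lists. That test replaced one on the lists without their lowest members, which a median makes uninformative. Loss of METTL5, a difference between the cultures and an error of a single library stay open and untested, so an effect of the knockout on this group may be put only as a hypothesis.

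Whether the number of protein-coding genes at least 2-fold apart comes in part from ratios of few reads could not be decided. Of the ratios from 5 to 100, 76.7% in the vector and 73.55% in the knockout lay on simple fractions of a single step (21.85 and 23.89), against at most 42.1% and 46.8% for decoy steps, as whole read numbers divided by each other would give. Among ratios of at least 1, the steps of 1 or 2 footprint reads held 38.3% of 791 from the higher genotype of 2-fold genes. They held 37.2% of 6130 others, a nearly equal share. Against decoy steps (26.6% and 32.9%) the excess differed by 7.343 percentage points (bootstrap interval over ratios 3.82 to 10.98). Smaller ratios hit decoy steps more often, and the 2 groups were not matched on the ratio. The difference therefore cannot tell few reads from the size of the ratio. Among 191 genes of 4 families that liver cells make abundantly, 5.236% were 2-fold apart, against 13.1% to 24.1% in random lists. Most of the other gene lists also had a share below that range, though the cell cycle and histone lists did not. Abundance was not measured and these random lists were not matched on the ratio, so the low share does not single out abundant genes. Ratios below 1 were not tested on steps, no count was assigned to a gene, and how many of the 2-fold genes reflect the knockout stays open.

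Higher ratios of 109 nuclear small RNAs (median log2 fold 1.13, 83 above 0) have no translation to reflect. A rise of all short structured RNA by the same amount in the knockout footprint library is argued against by the 12 mitochondrial transfer RNAs. Their median lay 2.021 below (bootstrap interval 0.30 to 2.96). The interval of their own median was -1.71 to 0.80, so a smaller rise of these RNAs is not excluded. All intervals in this paragraph come from resampling genes and hold no error between libraries. A ratio also cannot tell a footprint change from an input change. A detection limit of few input reads that differs between the genotypes is argued against for 15 of the small RNAs, whose ratios, on this reading of the steps, are too low to rest on 5 or fewer input reads and whose median was 0.9896 (interval 0.67 to 1.77). For the other 94 it cannot be told apart from other causes, since the step is known too coarsely to place large ratios and 8 protein-coding genes on such steps were 0.7807 above 215 others (interval -0.23 to 1.91). The 98 small RNAs not found on steps of so few reads had a median of 1.05. This decides nothing, because most of them are among the 94. A change in nuclear RNA in the lysate and an effect of METTL5 loss stay open and untested.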
